A study of Mus musculus with 4 samples.

How the data were processed

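ATAC-seq was performed on sorted lung ILC2s of 2 WT and 2 KO pools of mice. Per the labels' protocols, female mice were used unless otherwise stated and libraries were made with a transposase-based kit. The authors deposited 1 table of raw counts per peak, with chromosome, start and end of each peak and a column per library. The unit is taken from the table's sheet name and from its values, which are whole numbers with different totals. Per the submitters' processing notes, the genome build was mm10 and the tools were fastp, Bowtie2 2.5.3, MACS2, bedtools 2.31.1, ChIPseeker 1.28.3, deepTools 3.5.4 and edgeR 3.34.0. Their settings are not given in the sources used here, nor whether insertion sites were shifted, duplicates removed, reads or fragments counted, or peaks called on single or pooled libraries. Peaks called on pooled reads of both genotypes and peaks called per library would give a different set of weak peaks. Coordinates are printed as the table gives them, and whether they count from 0 or 1 is not stated.

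Samples were grouped by genotype from their labels. Both replicate numbers occur in both genotypes, and nothing in the labels says that a number marks a shared litter or day. Each peak was assigned to the protein-coding gene whose body holds its centre, or otherwise to the nearest gene body, in the RefSeq table of GRCm38, the assembly that mm10 names. That table gives gene starts and ends without strand. Start sites were therefore unknown, and the nearest gene body and the class of peaks centred within 1000 bp of either gene end took the place of the nearest start site and the promoter class planned before the data were examined. Peaks centred in 2 or more genes made up 1.24%. An assigned gene is a neighbour, not a shown target. Zfp683 was absent from that table, and the other listed genes were matched by symbol. No genome sequence was used here, so the planned motif tests and GC corrections were not run.

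Differential accessibility was tested in R 4.3.3 with edgeR 4.0.16. Peaks were filtered by filterByExpr, which left 50665 of 57203, and scaled by TMM. Robust quasi-likelihood fits of genotype gave p-values, adjusted by Benjamini-Hochberg with a threshold of 0.05. The biological coefficient of variation was 0.214. Standard errors were derived from the fold change and the F statistic. CPM values use TMM-scaled totals. Replicates are pools of different mice, so the spread between them includes that between pools. A chi-square per degree of freedom of 6.99 between the WT libraries and 6.79 between the KO libraries showed replicates to be separate libraries. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. With an estimated correlation instead, camera uses only the residual degrees of freedom of the libraries, which are few here. A list or class can then hardly pass, so failing that check decides nothing. The value of a list is its median log2 fold change minus the median of all tested peaks. Replicate agreement was computed on the same log2 CPM.

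Named peaks were to be, per direction, the 15 with the smallest adjusted p among passing peaks whose libraries separate by genotype, 1 per gene and without predicted genes. To these came up to 4 passing peaks per list and direction, and the peak with the smallest p of each of 14 fixed genes, of which 1 is not reported here. As no peak passed, the first part was applied without the threshold, and list members are named by smallest p or as examples. Both choices were made after the values were seen.

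Alternatives were DESeq2 1.42.0, other scalings and filters, a minimum fold of 2, a test against a fold of 1.2, a replicate block, leaving out each library (the one left alone in its genotype is then assumed to vary like the other pair), and for lists fry, sums per gene and other assignments. The fits were tested on simulated counts for 50665 peaks with 200 changed, where 4 of 92 calls were false. Of peaks above the median CPM, the test recovered 28.6% of those changed 2-fold and 95.3% of those changed 4-fold. The counts were drawn with the dispersion trend only, without peak-specific spread or a shared effect of the replicate number. In simulated lists of 100 peaks, a shift of 0.3 log2 units was called and 0 of 17 unshifted lists were. These lists held random peaks drawn independently, so they do not test the preset correlation. The shift was also larger than the value of any real list in the main fit.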

Results

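Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts adapters into open chromatin, in group 2 innate lymphoid cells (ILC2s) from mouse lung. The series asks how ILC2s are regulated by Brg1, the ATPase of the SWI/SNF chromatin remodelling complex, which is encoded by Smarca4. Cells lacking lineage markers and positive for CD45 and RFP were sorted from mice with Cre under Il5 and either wild-type Smarca4 alleles (WT) or floxed Smarca4 alleles (KO). The mice received papain, a protease that elicits type 2 lung inflammation, through the nose on each of 3 days, at a daily dose of 30 μg. Cells were taken after a rest of 2 months and are called memory ILC2s in the labels. Each of the 2 WT and 2 KO libraries came from its own pool of about 50000 cells from 2 to 4 mice. The counts over 57203 peaks summed to 8431301 and 11708969 in the WT libraries and to 11038082 and 8825096 in the KO libraries. Peaks had a median width of 1203 bp. Across peaks, the Pearson correlation of log2 CPM was 0.954 between the WT libraries and 0.956 between the KO libraries, and it lay between 0.939 and 0.960 for pairs of unlike genotype, so libraries of one genotype were no more alike than libraries of different genotypes. Peaks are not independent replicates.

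At the targeted gene, 3 tested peaks on chromosome 9 (mm10) were assigned to Smarca4, and none passed the test. The peak at 21615232 to 21617689, near an end of the gene, had 31.1 ± 2.13 CPM in WT and 32.7 ± 1.86 CPM in KO (mean ± SD, n = 2 each), a log2 difference of 0.074 with SE 0.21 that ran from 0.0027 to 0.15 when 1 library was left out. With scaling factors from peaks near gene ends, the sign of this difference turned to -0.029. The peak inside the gene at 21626497 to 21627326 had 2.57 CPM in WT and 4.06 CPM in KO, and the peak at 21609262 to 21610700, 6125 bp outside the gene, had 40.7 and 49.0 CPM, a log2 difference of 0.26 that turned to -0.026 without KO replicate 2. The floxed exons were not located here, so these peaks check neither the deletion nor the labels.

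The comparison of KO with WT asks which regions open or close when Smarca4 is deleted in Il5-expressing cells. The 2 peaks with the smallest p-values, at Rgs9 and near Casp12, were less accessible in KO and lay away from gene ends, though neither passed the test. The peak near Casp12 lies within 25 Mb of Smarca4, where DNA carried along with the floxed allele is an open explanation, considered below. Inside Rgs9, which encodes a regulator of G protein signalling, the peak on chromosome 11 at 109259382 to 109260895 had 25.9 ± 0.0156 CPM in WT and 5.97 ± 0.520 CPM in KO (SD, n = 2), a log2 difference of -2.12 with SE 0.26. The peak on chromosome 9 at 5394726 to 5396408, 22533 bp from Casp12, a gene of the inflammatory caspase cluster, had 7.41 ± 1.76 CPM in WT and 0.556 ± 0.123 CPM in KO (SD, n = 2), a log2 difference of -3.69 with SE 0.47. Neither passed edgeR's quasi-likelihood test of genotype alone after Benjamini-Hochberg adjustment (adjusted p = 0.106 for both). DESeq2's Wald test called exactly these 2 peaks, with adjusted p of 2.26e-05 at Rgs9 and 0.000487 near Casp12. Of 50665 tested peaks, edgeR called 0 higher and 0 lower in KO in this fit of genotype alone. With a block for the replicate number it called 29 higher and 122 lower, and 11.5% of peaks had an unadjusted p under 0.05. The labels do not say that the numbers pair the pools, so the block was kept as an alternative. Without the block, 692 higher and 1871 lower peaks had an unadjusted p under 0.05, 5.06% of those tested. That is about the share that a calibrated test gives by chance at that threshold. A split that mixes the genotypes, WT replicate 2 and KO replicate 1 against the other libraries, gave 681 such peaks in all, against 2563 for genotype. The split by replicate number gave 6001. The threshold is therefore no sure measure of what chance gives in this fit. At an unadjusted p under 0.01 there were 456 lower and 78 higher peaks, against 409 and 137 with loess offsets and 640 and 38 with factors from gene-end peaks. At p under 0.01 the split that mixes the genotypes gave 68 peaks in one direction and 12 in the other. The split by replicate number gave 2141 and 429, so unequal directions were not particular to genotype. Leaving out 1 library leaves its genotype with 1, which is then assumed to vary like the pair of the other genotype. On that assumption the counts at p under 0.01 were 389 lower and 248 higher without WT replicate 1, 602 and 616 without WT replicate 2, 285 and 90 without KO replicate 1, and 308 and 32 without KO replicate 2. On the same assumption edgeR called 5 higher and 22 lower peaks after adjustment without WT replicate 1, and 1 higher and 3 lower without WT replicate 2, which had 2055 higher peaks at an unadjusted p under 0.05. In simulated data with 200 changed peaks, the test recovered 17% of those changed 2-fold and 71% of those changed 4-fold. The simulated spread followed the abundance trend alone, without spread particular to a peak or an effect of the replicate number. Recovery in the real data may therefore differ. At these settings most changes of 2-fold were not detected with 2 libraries per group.

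**Figure D1:**
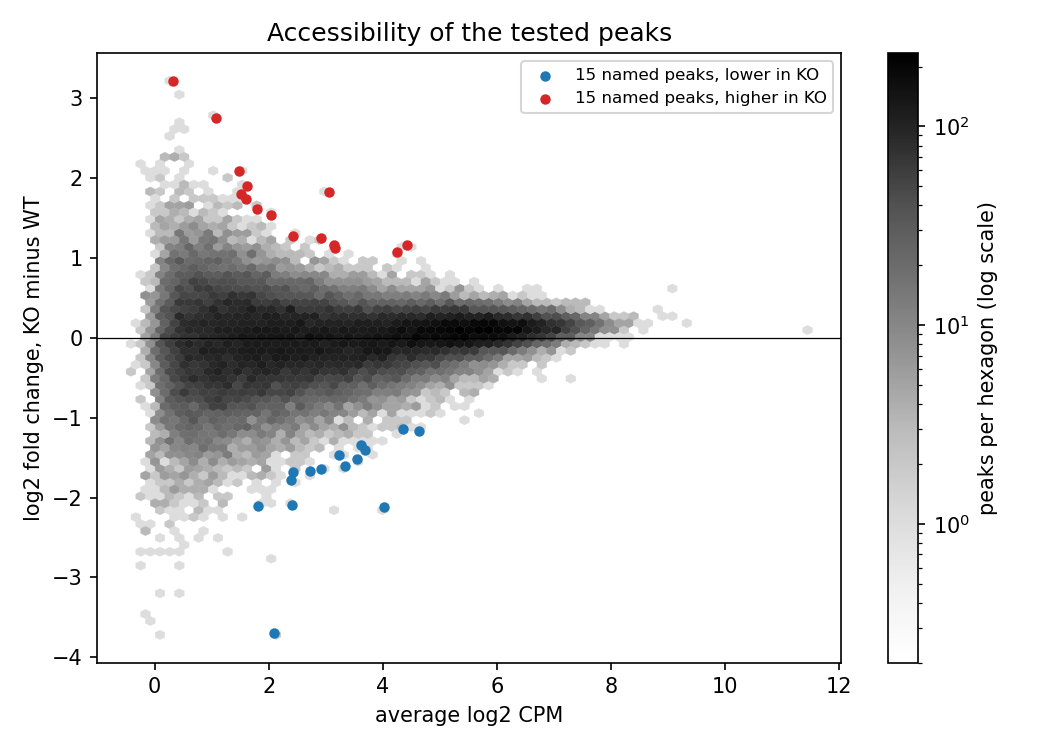
Each hexagon counts tested peaks by average log2 CPM (x axis) and log2 fold change of KO over WT (y axis), with darker shades for more peaks on a log scale. Blue and red points are the 15 peaks per direction with the smallest p, picked after their values were seen. None of them passed edgeR at an adjusted p of 0.05 without the replicate block.

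Since no peak passed, the rule for naming peaks was applied without its threshold, which was decided after the values were seen. None of the following peaks passed without the replicate block, while 15 of the 15 lower and 4 of the 15 higher peaks passed with it. The block fit tests the same contrast on the counts by which the peaks were picked, so this is no independent support. In the 15 peaks taken in the lower direction, log2 differences ran from -1.14 at Atp9b to -3.69 near Casp12. Beside Rgs9, they included a peak 29691 bp from Rgs8, another regulator of G protein signalling, with 5.35 ± 0.661 CPM in WT and 1.23 ± 0.0794 CPM in KO (SD, n = 2). The peak in Tln2, which encodes a talin linking integrins to actin, had 17.4 ± 0.239 CPM in WT and 6.85 ± 0.0575 CPM in KO (SD, n = 2). The peak in Ankrd44 had 34.0 CPM in WT and 15.2 CPM in KO. The others were assigned to Eea1, which encodes an early endosome protein, and to Rhbdl3, Nudt4, Sestd1, Tiam2, Zmat4, Srp9, Ctdp1 and Fank1. In the 15 peaks taken in the higher direction, log2 differences ran from 1.08 at Mgll to 3.22 at Wnk1, where both WT libraries held 2 counts. The peak 162 bp from Mn1 had 3.57 ± 0.528 CPM in WT and 12.7 ± 3.73 CPM in KO (SD, n = 2). The peak near an end of Mgll, which encodes monoacylglycerol lipase, had 12.1 ± 1.59 and 25.6 ± 7.12 CPM (SD, n = 2). The peak in Adam8, a metalloprotease gene, had 1.31 and 4.43 CPM. The others were assigned to Syt16, Tmprss11e, Sesn3, Nsl1, Hace1, Obsl1, Cplx2, Vash1, Sybu, Chrnb3 and Galr1. The Sesn3 peak, like that near Casp12, lies within 25 Mb of Smarca4. The smallest unadjusted p was 3.11e-06 in the lower direction and 0.000148 in the higher direction. The libraries of these peaks do not overlap between genotypes by construction, and 33.9% of all tested peaks showed such separation where chance gives 33.3%.

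**Figure D2:**
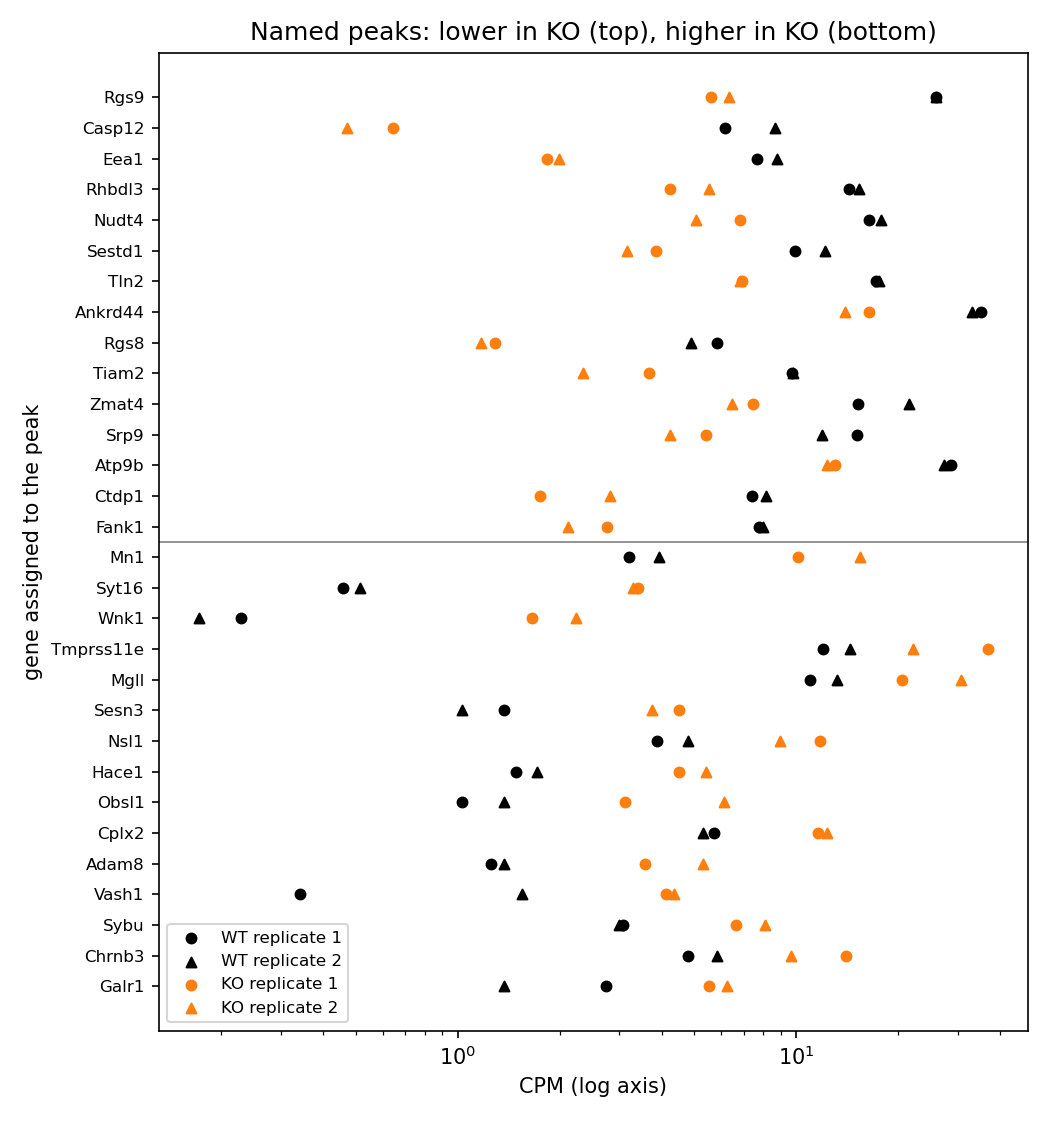
CPM (x axis, log scale) of the named peaks in each of the 4 libraries, with WT in black, KO in orange, circles for replicate 1 and triangles for replicate 2. At Rgs9 the WT libraries lie at 25.9 CPM and the KO libraries at 5.61 and 6.34 CPM.

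The fixed genes had no peak past the threshold in the fit without the replicate block. Many are ILC2 genes, while Tbx21 was listed with type 1 ILC and NK genes and Bach2 with immediate early genes. Rora, which encodes a transcription factor required for ILC2 development, had 66 tested peaks, of which 9 were lower and 0 higher at an unadjusted p under 0.05. Its peak with the smallest p, inside the gene on chromosome 9 at 68688300 to 68689928, had 13.4 ± 0.129 CPM in WT and 5.59 ± 0.892 CPM in KO (SD, n = 2), a log2 difference of -1.26 with SE 0.29. This peak had an adjusted p of 0.929 over all peaks and of 0.0338 over the Rora peaks alone, from edgeR. The adjustment over a gene's own peaks was made for each of the 14 fixed genes, with no correction across genes. For the others, the smallest adjusted p of this kind by edgeR ran from 0.347 at Smarca4 to 0.951 at Il1rl1. Over the 66 Rora peaks the median log2 difference was -0.043. Gata3, the lineage-defining factor of type 2 lymphocytes, had 84 peaks with a median log2 difference of 0.0038, of which 2 were lower and 1 higher at an unadjusted p under 0.05. The one with the smallest p, 172752 bp from the gene, had 51.2 ± 1.16 CPM in WT and 76.2 ± 13.9 CPM in KO (SD, n = 2). For the type 2 cytokine genes, the peaks with the smallest p differed on the log2 scale by 0.13 with SE 0.20 at Il5, 0.43 with SE 0.36 at Il13 and -0.27 with SE 0.35 at Il4. Without WT replicate 1, the values at Il5 and Il13 turned to -0.037 and -0.035. For the alarmin receptor genes, the values were 0.44 with SE 0.26 at Il1rl1 and 0.21 with SE 0.30 at Il17rb. They were 0.27 with SE 0.21 at Areg, which encodes amphiregulin, -0.58 with SE 0.29 at Klrg1 and -1.51 with SE 0.58 at Icos. At Bach2 and Tbx21, which encode transcription factors, they were -0.68 with SE 0.28 and -0.34 with SE 0.30. The Icos peak lay 71343 bp from the gene and held few counts, 20 and 34 in WT and 14 and 4 in KO. The value at Il17rb turned to -0.015 without WT replicate 2, and that at Tbx21 turned to 0.12 without WT replicate 1. Without WT replicate 1 and without WT replicate 2, respectively, the values were 0.0037 and 0.59 at Areg, 0.23 and 0.69 at Il1rl1 and -0.40 and -0.12 at Il4, and without WT replicate 2 that at Il13 was 1.17. Without KO replicate 1 and without KO replicate 2, they were -2.44 and -1.03 at Icos, -1.14 and -0.34 at Bach2 and 0.38 and 0.74 at Gata3. Each of these values is from 1 peak per gene, that with the smallest p. Medians over all tested peaks of a gene were 0.031 at Il5, -0.032 at Il13 and -0.17 at Il4. They were 0.034 at Il1rl1, 0.18 at Il17rb, -0.0022 at Areg and -0.14 at Klrg1. At Icos, Bach2 and Tbx21 they were 0.032, -0.058 and -0.14. The median and the single peak thus differed in sign at Il13, Areg and Icos.

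Of the 18 gene lists fixed before the data were examined, none differed from the other tested peaks by camera after adjustment. Without the replicate block, 0 peaks of any list passed over all peaks or adjusted over the list alone. The list of inhibitory receptors and exhaustion genes came nearest. Its 94 peaks had a median log2 difference of -0.077 relative to that of all peaks (adjusted p = 0.112, and adjusted p = 0.875 with an estimated correlation). Over all 50665 tested peaks, 1871 were lower and 692 higher at an unadjusted p under 0.05, so an excess of lower peaks is not particular to a list. At that level, 9 peaks of this list were lower and 0 higher. They included a peak assigned to Lag3, an inhibitory receptor gene, with 20.6 ± 0.908 CPM in WT and 8.49 ± 3.20 CPM in KO (SD, n = 2), and one assigned to Pdcd1, which encodes PD-1, with 6.75 and 3.40 CPM. Among the 103 peaks of type 2 effector genes, 6 were lower and 1 higher at that level (adjusted p = 0.314). Peaks assigned to the cytokine genes Il3 and Lif had 13.0 and 5.51 CPM in WT and 5.79 and 1.64 CPM in KO. Among the 592 peaks of ILC2 transcription factor genes, 33 were lower and 6 higher (adjusted p = 0.604). A peak assigned to Id2, which encodes an inhibitor of E proteins, had 9.39 and 4.27 CPM. Among the 231 peaks of ILC2 receptor genes, 10 were lower and 0 higher (adjusted p = 0.972). Among the 241 peaks of immediate early genes, 10 were lower and 8 higher (adjusted p = 0.678). A peak in Fosb, a gene of the AP-1 family, had 156 ± 3.08 CPM in WT and 215 ± 8.33 CPM in KO (SD, n = 2). Without WT replicate 1, the type 2 effector and inhibitory receptor lists passed, with values of -0.18 and -0.14, from 1 WT library against 2 KO libraries, but neither did with an estimated correlation (adjusted p = 0.958 for both). The first turned to 0.042 without WT replicate 2. With counts summed per gene, the inhibitory receptor list passed at -0.14, and it did not with an estimated correlation (adjusted p = 0.782). With an estimated correlation a list can hardly pass with so few libraries, so these failures decide nothing.

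The remaining lists did not pass either. Adjusted p was 0.625 for migration and tissue residency, 0.987 for survival, 0.866 for the cell cycle, 0.625 for glycolysis, 0.314 for lipid metabolism and 0.678 for SWI/SNF subunits. The marker lists of other cells, of which the sort for CD45 and against lineage markers is meant to remove many, had adjusted p of 0.625 for type 1 ILCs and NK cells, 0.314 for ILC3s, 0.911 for T cells, 0.911 for B cells, 0.911 for myeloid cells, 0.625 for eosinophils, mast cells and basophils and 0.987 for lung epithelium, endothelium and stroma. Of the 95 peaks of type 1 ILC and NK genes, 8 were lower and 0 higher at an unadjusted p under 0.05. They included a peak near an end of Ccl5, a chemokine gene, with 10.1 ± 1.26 CPM in WT and 4.94 ± 0.678 CPM in KO (SD, n = 2). This list passed with counts summed per gene, at -0.23 (adjusted p = 0.00396), and with peaks near gene ends only, at -0.55 (adjusted p = 2.32e-05). With an estimated correlation, where a list can hardly pass with so few libraries, it passed in neither (adjusted p = 0.782 and 0.845). Without WT replicate 1 its value turned to 0.037. The median and the mean of the B cell list differed in sign, at 0.14 and -0.16 relative to all peaks. They also did so for the myeloid, survival, ILC2 receptor and lung epithelial lists.

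**Figure D3:**
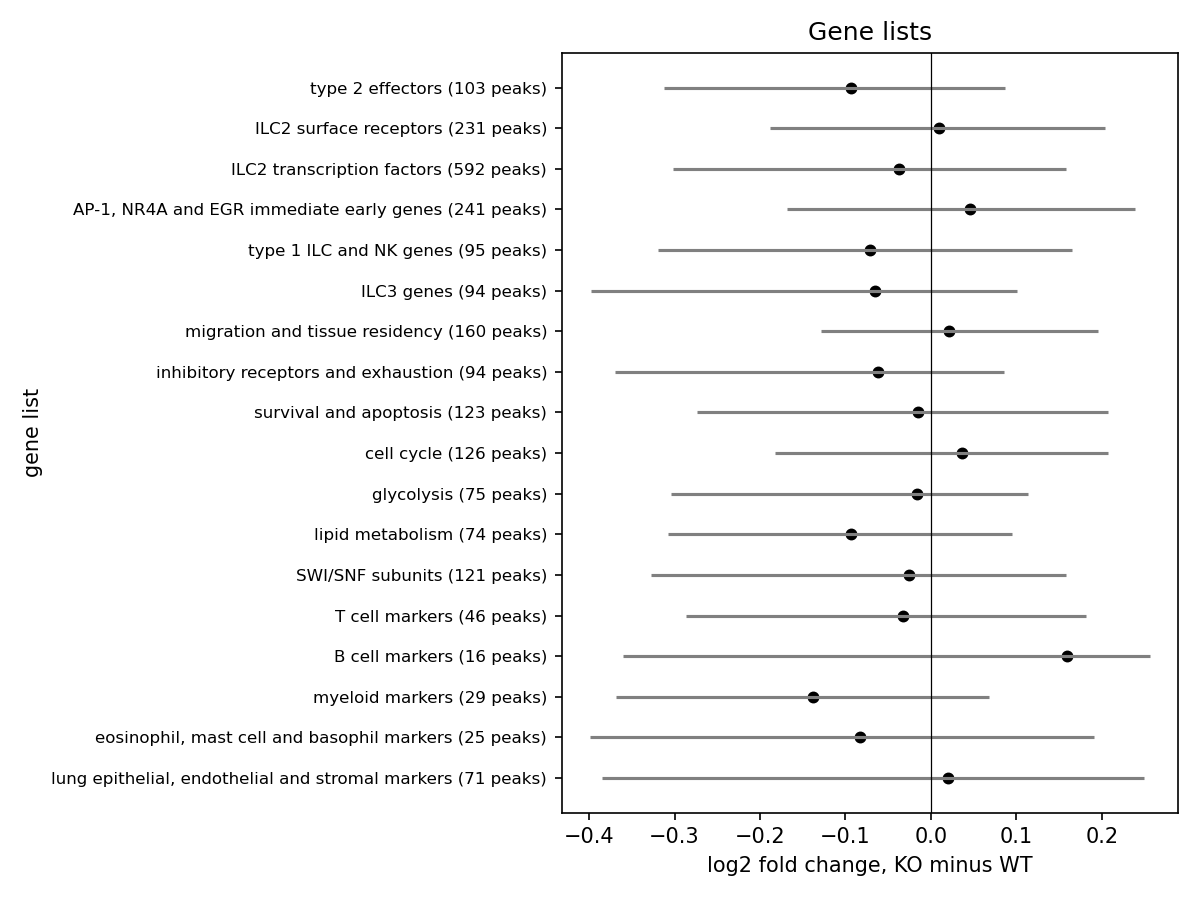
Median (points) and quartiles (lines) of the log2 fold change of KO over WT (x axis) across the tested peaks of each gene list (y axis), with the number of peaks in brackets. The quartile range of every list spans 0.

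Peaks near gene ends and other peaks differed in their fold changes. The 11592 tested peaks centred within 1000 bp of an end of a protein-coding gene had a median log2 difference of 0.11, against -0.042 for the 22548 other peaks inside genes and -0.035 for the 16525 intergenic peaks. The difference between the gene-end class and the rest was 0.15 log2 units (camera p = 1.56e-06 with the preset correlation, p = 0.0850 with an estimated correlation). With an estimated correlation a class can hardly pass with so few libraries. Of the peaks with an unadjusted p under 0.01 that were lower in KO, 17 lay at gene ends, 240 inside genes and 199 between genes, which was 0.147%, 1.06% and 1.20% of each class. The higher peaks made up 0.155%, 0.151% and 0.157%. No test of calls against class was made, since no peak passed. Peaks at gene ends held 44.8% and 47.4% of all counts in the WT libraries and 46.6% and 49.7% in the KO libraries, so the genotypes overlapped. The difference between the gene-end class and the rest was 0.063 without WT replicate 1 and 0.078 with loess offsets. The classes also differed in abundance, with a median CPM of 31.0 at gene ends, 5.21 inside genes and 4.87 between genes. Among 5 groups of tested peaks ordered by abundance, the median log2 difference was -0.072 in group 1, the least abundant, and 0.099 in group 5. The same-numbered pairs differed in this. KO replicate 1 minus WT replicate 1 was -0.186 in group 1 and 0.127 in group 5. KO replicate 2 minus WT replicate 2 was 0.0757 in group 1, -0.0324 in group 3 and 0.0671 in group 5, so it showed no steady rise. Class and abundance were therefore not separated by these values.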

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

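The alternatives here were planned, except the estimated correlation for the gene-end class and for lists with sums per gene, with gene-end peaks or without WT replicate 1, the assignment to the nearest gene end and the removal of peaks within 25 Mb of Smarca4, which were chosen after seeing the data. For counts and list values below, the cause of a change was not tested unless fewer peaks or libraries were used. The edgeR count of 0 higher and 0 lower peaks held with DESeq2 size factors, library sizes, loess offsets, no filter, a stricter filter, a minimum fold of 2, a test against a fold of 1.2, a fit without robust estimation and the peaks away from Smarca4. It became 0 higher and 2 lower with factors from gene-end peaks and with DESeq2's Wald test. Leaving out 1 library gave 0 to 5 higher and 0 to 22 lower peaks. At an unadjusted p under 0.05 (692 higher and 1871 lower), counts were 349 higher with factors from gene-end peaks, 288 higher and 901 lower with DESeq2, 242 and 984 with the stricter filter, 335 and 939 with a minimum fold of 2, and 456 higher against a fold of 1.2. Without 1 library they ran from 462 to 2055 higher and 1316 to 2008 lower. At p under 0.01 (78 and 456), counts were 86 and 434 with DESeq2 size factors, 52 and 581 with library sizes, 35 and 222 with DESeq2 and 17 and 251 with the stricter filter. In fits without 1 library, the library left alone in its genotype is assumed to vary like the other pair.

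The replicate numbers are not stated to pair the pools, and there are 2 pairs, so the block is a hint from the data only. Deviations of same-numbered libraries correlated at 0.239 across peaks. With the replicate block, edgeR called 29 higher and 122 lower peaks, with 2790 higher and 3015 lower at an unadjusted p under 0.05 and 843 and 1164 at p under 0.01. Of the named peaks, 15 of 15 lower and 4 of 15 higher were among those calls, which is no independent support, as they were picked by genotype in the same counts. Within 25 Mb of Smarca4, 10 of 804 peaks were called, against 141 of 49861 elsewhere (two-sided Fisher exact p = 0.000161, with neighbouring peaks not independent). That share was reached by 0.0389% of other windows, which overlap one another and are not independent. Without the peaks at 5.2 to 5.6 Mb, 7 of 795 were called (exact p = 0.00912). The block turned the lung epithelial, endothelial and stromal list to -0.0062, and no list passed with it. Single peaks of the lists did (adjusted p from 0.0159 to 0.0471), so counts of 0 for the lists and for ILC2 genes hold without the block only: lower peaks assigned to Lag3, Ccl5, Il1r2, Id2, Rora, Lpin1, Il2, Hilpda, Il3 and Myc, and higher peaks assigned to Fosb and Gata3.

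Mixed fry, which asks for changes in either direction, passed the inhibitory receptor (-0.077), B cell (0.14) and myeloid (-0.15) lists at an adjusted p of 0.0366. With an estimated correlation a list or class can hardly pass with so few libraries, so the calls lost with it below decide nothing. Sums per gene passed type 1 ILC and NK genes (-0.23) and inhibitory receptors (-0.14), both lost with an estimated correlation (adjusted p = 0.782), and turned migration to -0.042, survival to 0.018, cell cycle to -0.0090, B cells to -0.052 and lung epithelium to -0.028. Gene-end peaks alone passed type 1 ILC and NK genes (-0.55), lost with an estimated correlation (adjusted p = 0.845), and turned survival to 0.011, lipid metabolism to 0.021, B cells to -0.017 and lung epithelium to -0.017. Peaks within 100 kb of a gene end turned migration to -0.020 and survival to 0.0095. Loess offsets turned the eosinophil, mast cell and basophil list to 0.0052. The value of that list ran from -0.38 to -0.034 when 1 library was left out, and that of the myeloid list from -0.26 to -0.058. Leaving out 1 library gave ranges from -0.20 to 0.042 for type 2 effectors, -0.19 to 0.037 for type 1 ILC and NK genes, -0.15 to -0.056 for inhibitory receptors, -0.018 to 0.075 for the cell cycle, -0.075 to 0.11 for ILC2 receptors, -0.024 to 0.064 for immediate early genes, -0.060 to 0.091 for migration, -0.027 to 0.050 for survival, -0.056 to 0.051 for T cells, -0.076 to 0.21 for B cells, -0.083 to 0.10 for lung epithelium and -0.10 to 0.023 for ILC2 transcription factors. Type 2 effectors (-0.18) and inhibitory receptors (-0.14) passed without WT replicate 1, both lost with an estimated correlation (adjusted p = 0.958). The gene-end difference of 0.15 lost its call with an estimated correlation (p = 0.0850) and stayed between 0.063 and 0.22 with its call under the others run for it, a class width of 3 kb, library sizes, DESeq2 size factors, loess offsets, the block, each left-out library and the peaks away from Smarca4. The peak near an end of Smarca4 turned to -0.029 with factors from gene-end peaks. Leaving out 1 library turned the peaks of Il5 (-0.037 to 0.32), Il13 (-0.035 to 1.17), Il17rb (-0.015 to 0.47) and Tbx21 (-0.69 to 0.12) and the outer peak of Smarca4 (-0.026 to 0.51). The WT correlation was 0.964 with log2(CPM + 1). Motif enrichment and GC offsets were not run, since no genome sequence was used here. With 2 libraries per group, depth of 8431301 to 11708969 counts and the spread between pools limit what could be detected.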

Other observations

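When counts were summed over the peaks of each of 14901 genes, a use of the sums chosen after seeing the data, edgeR called 0 genes, with 133 higher and 349 lower at an unadjusted p under 0.05. The smallest adjusted p was 0.279, at Casp12, whose 5 peaks summed to 148 and 219 counts in WT and 32 in each KO library (log2 difference -2.48, SE 0.28). Casp12 lies within 25 Mb of Smarca4, a region considered below. The genes next in order were Rgs8, with 6 peaks and a log2 difference of -1.62, Zmat4, with 14 peaks and -1.01, Tln2, with -1.20, and Mgll, with 5 peaks and 0.94. Further down were Itga9, which encodes an integrin subunit (-1.09), and Jdp2, which encodes a repressor of AP-1 (-0.51). None of these passed. Single genes could hold several low peaks: 5 of the 6 peaks of Rgs8 and 3 of the 5 peaks of Ccl5 were lower at an unadjusted p under 0.01, as were 5 of the 47 peaks of Id2 and 3 of the 66 of Rora.

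The tests below were chosen after the result was seen for the gene-end shift, for the windows around Smarca4, for the splits of the libraries and for the estimated correlation. Those with loess offsets between replicate numbers, with markers of other cells and without the Casp4 and Casp12 locus were fixed before their values were seen.

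Libraries with the same replicate number differed from those with the other number by more than the genotypes did. A fit of replicate 2 against replicate 1 called 1164 peaks, 1129 of them higher in replicate 2 and 888 of these at gene ends, while KO against WT and the remaining split each called 0. This points to a structure of the samples, and with 3 splits of 4 libraries no share under 0.05 can be reached (1 split gave as many, the highest other gave 0). An abundance trend is argued against as the whole cause, since loess offsets left 1587 calls. Other cells at a different share may contribute: 1 of 7 marker lists, that of type 1 ILCs and NK cells, of which a sort against lineage markers and for RFP, in mice with Cre under Il5, would remove those with such markers or without RFP, passed camera (adjusted p = 0.0295, and adjusted p = 0.886 with an estimated correlation), but 14 of its 19 genes moved down and 5 up in replicate 2, so the test left this open. No biological explanation was tested, as the labels attach none to the numbers.

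The higher accessibility of gene ends in KO, measured only relative to other peaks, could come from libraries that differ in signal over background whatever the genotype. The split by replicate number gave a shift of 0.129 log2 units, against 0.152 between genotypes and 0.00935 for the remaining split. Within replicate numbers, KO exceeded WT by 0.174 and 0.138, and within genotypes replicate 2 exceeded replicate 1 by 0.135 in WT and 0.116 in KO. An abundance-dependent scaling error stays open, since loess offsets left 0.0781 of the shift. An effect of Smarca4 deletion stays open too and cannot be separated from these with 2 libraries per genotype.

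Peaks with low p were more frequent near the targeted gene. In the fit without the replicate block, within 25 Mb of Smarca4, 16 of 804 tested peaks had p under 0.01, against 518 of 49861 elsewhere (1.99% and 1.04%, two-sided Fisher exact p = 0.0142, with neighbouring peaks not independent). A candidate explanation is DNA of another strain carried along with the floxed allele. Of 2568 other windows of up to that width, 7.01% had as high a share, more than the 5% set for the test, so that test left it open. Neighbouring windows overlap almost fully, and windows near chromosome ends, that of Smarca4 among them, are cut short. The percentage therefore rests on far fewer independent windows. Without the peaks at 5.2 to 5.6 Mb, where Casp4 and Casp12 lie, the share was 1.64% (two-sided Fisher exact p = 0.111), so whether that locus alone accounts for the excess was left open by that test as well. Values with the block are given with the other alternatives and were not used to settle either, since the numbers are not known to pair the pools. One peak in Cdc37, at 21146653 to 21147543 on chromosome 9, had 50 and 116 counts in WT and 0 and 11 in KO, and was picked after its values were seen. Genotypes of the flanking DNA were not analysed here, and deletion of Smarca4 stays among the untested explanations.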
